A study of Mus musculus with 6 samples.

How the data were processed

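Total RNA from mouse optic nerves was amplified with the NuGEN Ovation RNA-Seq System v2 and made into Nextera XT libraries, per the labels' protocols. The 6 libraries were 3 from control animals and 3 from animals with a tamoxifen-inducible Cre recombinase (PlpCreERT2) and 2 floxed Nf1 alleles. Adult animals received tamoxifen, and nerves were taken 1 month later. Control library 1 carries the genotype Nf1flox/flox and control libraries 2 and 3 carry Nf1flox/+, all without the Cre. Replicate numbers follow the order of deposit and pair no samples. The labels do not tie each library to a separate animal, so p-values measure the spread between these libraries, which may be technical in part.

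The deposited values are raw fragment counts per gene and library, with no normalization. Counts were made by the authors with featureCounts 1.4.6-p4 on paired reads over exons, without regard to strand, per the file headers. TopHat and the mm10 genome build are named in the submitters' processing notes, and the annotation was the UCSC mm10 gene set, per the file headers. Coordinates are those of the deposited files on mm10. Of the 24062 gene symbols in the files, none of the 26 names of mitochondrially encoded genes was found, so that list was not analysed here. Counting without strand cannot separate a gene from an overlapping partner. Exons of Grin1 overlap Grin1os and Lrrc26, those of Ppp1r1b overlap 1700003D09Rik, those of Tspan2 overlap Tspan2os, those of Srebf1 overlap Rai1, and those of Xist overlap Tsix. Exons of Evi2a overlap the read-through gene Evi2a-evi2b, those of Pdgfra overlap Mir7025, and those of Gucy1a3 overlap Mir7010. Values of these genes are uncertain to that extent, as are those of the related Trim genes, which can share reads.

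Total counts ranged from 13555756 to 23662698 per library. All pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 48.2, so each library was counted once. The main test was edgeR 4.0.16 (R 4.3.3) with quasi-likelihood F tests, TMM scaling, filterByExpr (minimum count 10) and no covariate. Benjamini-Hochberg adjusted p under 0.05 over the 16315 genes tested was the threshold. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. CPM values, counts scaled to library size, use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. PCR copies are not independent molecules, so counting intervals and floors cover counting error only. Where all libraries of a group had 0 counts, the fold was computed against a floor of 3 counts over the group.

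Tested on simulated counts drawn from the means of these libraries, with 16037 genes, the mutant against control test recovered 1.49% of genes changed 1.5-fold, 1.49% of genes changed 2-fold and 45.5% of genes changed 4-fold. It made 33 calls, of which 1 was false. Only 67, 67 and 66 genes were changed by these folds. The data gave 537 calls, so their cutoff on p was less strict and these rates may understate recovery in them. In simulated lists, the changed list had an adjusted p of 4.61e-33 and 0 of 30 unchanged lists were called. Genes were drawn independently there, whereas the correlation estimated in the data was up to 0.923, for the myelin list. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes.

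Fixed before the data were examined were the tests, the alternatives to them, 34 gene lists and the rule for naming genes. The rule named Nf1 and the genes in its introns, and up to 12 genes per direction with the smallest p. Those genes needed adjusted p under 0.05, an absolute log2 fold change of at least 1, groups that did not overlap, and a name other than a gene model or small RNA. From each list it named up to 4 members, those that passed first and then by smallest p. Some genes that the rule takes are not reported here. Mbp, Ppp1r1b and the genes named only in the closing section were chosen after their values were seen. Lists with 3 or more tested genes, 31 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The same lists were tested with an estimated correlation and with fry. Counts "adjusted over the list alone" use the members of 1 list as the family of tests. Shares of counts per list were compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

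Alternatives were DESeq2 size factors, upper quartile scaling, total counts, DESeq2 1.42.0 (the tool that the series names), limma-voom with and without quality weights, robust dispersion, other filters and thresholds, removal of blood, muscle, retina and lens genes, 1 surrogate variable from sva 3.50.0, the log2 CPM of Xist as a covariate, and leaving out each library. Chosen after seeing the data were mutant library 2 alone against the controls, the libraries with high Xist alone, the neuron list mean as a covariate, removal of Rn45s, scaling to the myelin list, and removal of X and Y genes.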

Results

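The transcriptome of the adult mouse optic nerve was compared between animals in which Nf1 had been targeted in mature oligodendrocytes and controls. Nf1 encodes neurofibromin, a GTPase-activating protein that lowers Ras activity. The comparison asks which transcripts of the nerve differ 1 month after tamoxifen. Control libraries 1, 2 and 3 held 21307855, 23662698 and 22872063 counts, and mutant libraries 1, 2 and 3 held 19012262, 13948624 and 13555756. The ribosomal RNA precursor Rn45s took 10.9%, 5.06% and 3.53% of counts in the controls and 4.97%, 8.21% and 1.73% in the mutants. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.957 to 0.973 between controls. Mutant library 2 had r of 0.932 to 0.943 with controls, whereas mutant libraries 1 and 3 had r of 0.870 to 0.884 with controls and 0.953 with each other.

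Nf1 (chromosome 11, 79339892 to 79581609, plus strand, 58 exons) had 377 ± 35.0 CPM in controls and 321 ± 104 CPM in mutants (SD, n = 3 each). The log2 fold change was -0.23 (SE 0.28), with an edgeR adjusted p of 0.703. Control libraries 1, 2 and 3 had 394, 400 and 337 CPM, and mutant libraries 1, 2 and 3 had 304, 226 and 433 CPM, so the groups overlapped. Counts over the whole gene do not resolve the deleted part and do not check the labels. Omg and Evi2a, which lie in introns of Nf1 on the opposite strand, had log2 fold changes of -0.04 (SE 0.30, adjusted p 0.966) and -0.68 (SE 0.53, adjusted p 0.527). Evi2b had 0 to 9 counts per library and was not tested, and the name Evi2 was not matched. Evi2a passed without mutant library 2, where its log2 fold change was -1.70 and its adjusted p 0.000752, while that of Omg was -0.40 and did not pass. Both genes are also members of the list of myelin and mature oligodendrocyte genes, whose median was -2.21 in that fit. The value of Evi2a is thus not particular to the Nf1 locus.

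The 12 genes with the smallest p among those that rose included both main dopamine receptor genes. Drd2, the D2 dopamine receptor (chromosome 9, 49340662 to 49407214), went from 1.32 ± 0.220 to 41.8 ± 12.2 CPM, a log2 fold change of 4.97 (SE 0.34). Drd1a, the D1 receptor (chromosome 13, 54051183 to 54055658), went from 5.40 ± 1.12 to 108 ± 34.8 CPM, a log2 fold change of 4.33 (SE 0.34). Penk, the precursor of enkephalins (chromosome 4, 4133536 to 4138445), went from 12.2 ± 3.09 to 265 ± 95.1 CPM, a log2 fold change of 4.44 (SE 0.36). Pde10a, a cyclic nucleotide phosphodiesterase, went from 43.7 ± 10.4 to 577 ± 165 CPM. Ddn, a postsynaptic protein gene, rose by 6.45 on the log2 scale, the adenosine receptor gene Adora2a by 4.35, and the G protein subunit gene Gng7 by 2.81. The transcription factor gene Egr3 rose by 4.80, Adamts3 by 4.90, Sez6 by 3.93, Syndig1l by 3.87 and Rasd2 by 3.49. All 12 were higher in each of the 3 mutant libraries than in any control, with edgeR adjusted p of 0.00143 to 0.00161. Ppp1r1b, a regulator of dopamine signalling, also rose, by 3.41 (SE 0.37, edgeR adjusted p 0.00278). Drd2, Drd1a, Gng7, Adora2a, Penk, Pde10a, Rasd2 and Ppp1r1b are members of a list of striatal projection neuron genes described in the closing section. Neural tissue from outside the nerve stays open as a source of these transcripts, so their rise is not shown to be a change within the nerve.

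**Figure D1:**
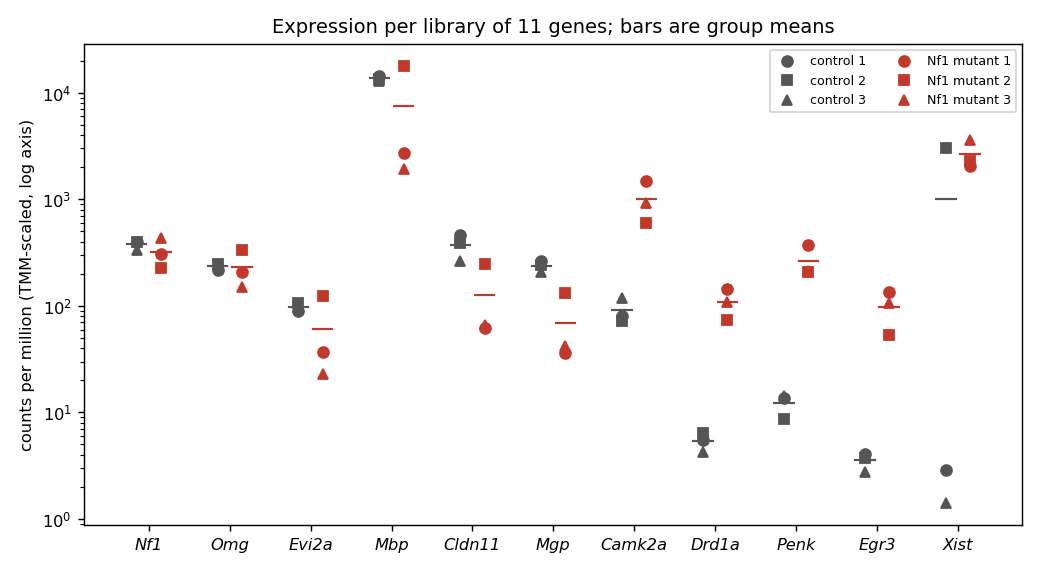
CPM (log axis) of 11 genes in 3 control libraries (grey) and 3 Nf1 mutant libraries (red), with bars at group means. Drd1a, Penk and Egr3 were higher in each mutant library than in any control, Nf1 overlapped between groups, and Mbp was 17890 CPM in mutant library 2 against 2719 and 1939 CPM in mutant libraries 1 and 3.

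The genes that fell were fewer and included Sytl4, a vesicle trafficking gene on chromosome X, with 26.4 ± 7.74 CPM in controls and 3.46 ± 1.11 CPM in mutants. Its log2 fold change was -2.94 (SE 0.38, edgeR adjusted p 0.00613). Clec14a, an endothelial lectin gene, fell by 2.12, Eya1 by 1.51, the small heat shock gene Hspb1 by 2.15, and the matrix gene Postn by 1.37. H60b, a ligand gene of natural killer cell receptors, fell by 2.85, Fbxw15 by 2.67, Tsku by 1.86, the retinol transporter gene Stra6 by 1.78, and Sspo by 2.63. Trim12a (chromosome 7, 104299897 to 104315495) had 562 counts over the controls and 7 over the mutants. Prdm13 had 172 counts over the controls and 0 over the mutants, at least 38.6-fold lower against a floor of 3 counts over the group. Adjusted p of these 12 genes ranged from 0.00613 to 0.0260. Each of them lost its call without at least 1 library, Sytl4 only without control library 1 (adjusted p 0.0604).

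Of 16315 genes tested, 537 changed, 482 upward and 55 downward, each by at least 2-fold, and 3133 had an unadjusted p under 0.05. The groups did not overlap in 3908 genes, 24.0% of those tested, where chance gives 10%. The biological coefficient of variation was 0.362. The count of 537 was 51, 81 and 112 without control libraries 1, 2 and 3, and 164, 4551 and 199 without mutant libraries 1, 2 and 3. With the log2 CPM of Xist as a covariate it was 0 by edgeR, with 1304 genes at an unadjusted p under 0.05. Scaling to the myelin list, chosen after seeing the data, gave 3179 genes higher and 4 lower in place of 482 and 55.

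Xist, which is expressed from the inactive X chromosome, had 58, 72727 and 34 counts in control libraries 1, 2 and 3, and 38466, 30602 and 51760 counts in mutant libraries 1, 2 and 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 1279 to 2206 counts in control libraries 1 and 3. They had 0 counts, which allows up to 3, in control library 2 and all 3 mutant libraries. The sex-linked list had 2 tested members, Xist and Tsix, of which neither passed. Xist had a log2 fold change of 1.41 (SE 1.92, edgeR adjusted p 0.736). Sex marker expression thus differed within the controls and was of 1 kind in the mutants, and 15 of the 537 changed genes lie on the assembled X or Y. That count, and the removal of X and Y genes, leave out separate contigs of X, where the changed gene Spry3 lies. Among the libraries with high Xist alone, chosen after seeing the data, 0 genes passed by edgeR and 894 had an unadjusted p under 0.05, but with 1 control library this loss of calls decides nothing. There the 482 genes had a median log2 fold change of 2.55 (median SE 0.74) against 2.44 (median SE 0.41), and the 55 had -2.05 (median SE 0.66) against -1.97 (median SE 0.39). Both sets were called from a comparison that held these same libraries, so their kept fold changes are no test of sex.

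Neuron genes were higher in the mutant libraries. Of 23 tested members 6 rose, or 15 adjusted over the list alone, and the median log2 fold change was 1.66. Camk2a, a synaptic kinase gene, went from 90.5 ± 24.98 to 998 ± 445 CPM (log2 fold change 3.46, SE 0.40, edgeR adjusted p 0.00451). Rbfox3, which encodes the neuronal nuclear antigen NeuN, rose by 3.09, the glutamate receptor gene Grin1 by 1.97 and the synaptic vesicle gene Syt1 by 2.95. The camera adjusted p was 6.15e-11, and adjusted p = 0.533 with an estimated correlation. Relative to the control mean, the list mean was 2.34, 0.44 and 1.60 log2 units in mutant libraries 1, 2 and 3, and 0.34 in control library 3. The list took 0.163% ± 0.0551 of counts in controls and 0.647% ± 0.333 in mutants (n = 3 each, exact permutation p 0.1, the smallest possible; 0.267 adjusted over 16 lists).

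Immediate early genes, which respond to cell stimulation within minutes, were also higher. Of 23 members 5 rose, or 12 adjusted over the list alone, and the median log2 fold change was 1.35. Fosb went from 0.574 ± 0.287 to 11.4 ± 5.13 CPM (log2 fold change 4.32, SE 0.57, edgeR adjusted p 0.00707). Npas4 rose by 3.55 and Egr4 by 5.79, beside Egr3. The camera adjusted p was 2.76e-07, and adjusted p = 0.533 with an estimated correlation. The list mean stood 1.82, 1.07 and 1.10 log2 units above the control mean in mutant libraries 1, 2 and 3, where the neuron list stood at 2.34, 0.44 and 1.60. With the neuron list mean as a covariate, chosen after seeing the data, the median was 0.74, 17 of the 23 kept their sign and 1 passed, Egr3. The 2 lists of striatal projection neuron genes in the closing section share 0 genes with the neuron list. They stood at 4.41, 3.69 and 3.89 and at 1.89, 1.25 and 1.80 log2 units in mutant libraries 1, 2 and 3. The covariate therefore cannot show whether the immediate early rise is separate from theirs.

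Genes of myelin and mature oligodendrocytes, the cell type targeted, had a median log2 fold change of -0.91. None of the 30 passed, and 0 passed adjusted over the list alone, although all 30 fold changes were negative. Cldn11, a tight junction gene of myelin, had 373 ± 103 CPM in controls and 125 ± 106 CPM in mutants (log2 fold change -1.57, SE 0.53, edgeR adjusted p 0.155). Values were -1.08 for Cd9, -1.24 for Aspa and -1.01 for Tspan2. Mbp, which encodes myelin basic protein, had a log2 fold change of -0.86 (SE 0.77, adjusted p 0.586). The list mean was -1.89 and -2.36 log2 units from control in mutant libraries 1 and 3 and 0.17 in mutant library 2, where the list median against controls was 0.20. The camera adjusted p was 2.51e-07, and adjusted p = 0.571 with an estimated correlation. Without mutant library 2 the list median was -2.21 and the 5 members named here passed, Mbp at -2.54 (adjusted p 5.65e-05) and Cldn11 at -2.53 (adjusted p 0.000112) among them, while the median was -0.56 and -0.53 without mutant libraries 1 and 3. The list took 3.90% ± 0.233 of counts in controls and 2.06% ± 2.15 in mutants (n = 3 each, exact permutation p 0.4). The mutant libraries had 0.858%, 4.53% and 0.779%, so that mean describes none of them, and the difference of -1.84 points was -3.08 without mutant library 2 and -1.20 without mutant library 3.

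Lipid genes of myelin and genes of the oligodendrocyte lineage showed smaller values. Of 24 genes of myelin lipid synthesis 0 passed by edgeR, or 0 adjusted over the list alone. Their median log2 fold change was -0.51, with Srebf1 at -1.04 and Elovl7 at -1.03 (camera adjusted p 0.00136; adjusted p = 0.571 with an estimated correlation). Of 24 cholesterol synthesis genes 0 passed in both families, with a median of -0.43 and Dhcr7 at -0.87 (camera adjusted p 0.00686; adjusted p = 0.571 with an estimated correlation). Markers of precursors and newly formed oligodendrocytes had 0 of 20 passing in both families, a median of -0.46, Itpr2 at -0.85 and Pdgfra at -0.68 (camera adjusted p 0.00394; adjusted p = 0.571 with an estimated correlation). The means of these lists in mutant library 2 were -0.03, 0.08 and -0.02 log2 units from control. Without mutant library 2 their medians were -0.87, -0.73 and -0.92. The cholesterol median was -0.29 without mutant library 1 and -0.20 without mutant library 3, where its call was lost (adjusted p 0.133).

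Astrocyte markers had no single direction. None of 20 passed, or 1 adjusted over the list alone, Gjb6, a connexin gene with 252 ± 42.2 CPM in controls and 97.2 ± 38.1 CPM in mutants (log2 fold change -1.37, edgeR adjusted p 0.0501). Slc1a2, a glutamate transporter gene, had a log2 fold change of 1.05, and Agt had -1.33. The list median was -0.31 and camera did not call it (adjusted p 0.0668), but called it on ranks (adjusted p 0.0444), without control library 2 (adjusted p 0.0400) and without mutant library 2 (median -0.58, adjusted p 0.00181). The median was -0.14 without mutant library 3, and camera gave adjusted p = 0.571 with an estimated correlation. Of 25 reactive astrocyte genes 1 fell, Hspb1, or 4 adjusted over the list alone, with a median of -0.93 and Cd44 at -1.39 (camera adjusted p 6.87e-08; adjusted p = 0.533 with an estimated correlation). Its mean was -1.76, -0.37 and -1.40 log2 units from control in mutant libraries 1, 2 and 3, and its median -1.72 without mutant library 2.

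Immune cell markers had 0 of 24 microglial genes passing, 0 adjusted over the list alone, and a median log2 fold change of -0.43. Ctss was at -0.67 and Cd53 at -0.94 (camera adjusted p 0.00771; adjusted p = 0.642 with an estimated correlation). The list mean was 0.25 in mutant library 2, without which the median was -0.94, and the call was lost without mutant library 3 (median -0.15, adjusted p 0.333). Of 19 tested markers of perivascular macrophages and other leukocytes, Cd4 rose by 3.23 (SE 0.59, edgeR adjusted p 0.0246) and was the 1 member that passed adjusted over the list alone. The list median was -0.87, with Lyve1 at -1.25 (camera adjusted p 0.0146; adjusted p = 0.571 with an estimated correlation), and -1.87 without mutant library 2. Its mean was -1.41, 0.30 and -1.10 log2 units from control in mutant libraries 1, 2 and 3, and -0.52 to 0.41 in controls. Ly6g was not matched. Camera did not call this list without control library 1 (adjusted p 0.0717) or without mutant library 1 (adjusted p 0.0569). Interferon-stimulated genes had 0 of 26 passing in both families and a median of -0.64, with Rsad2 at -0.99 (camera adjusted p 0.000437; adjusted p = 0.571 with an estimated correlation). Their mean was -1.10, 0.14 and -1.22 in the same order, and the median was -1.23 without mutant library 2 and -0.39 without mutant library 3.

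Fibroblast markers had the lowest median of the 31 tested lists, -1.48. Of 24 members 0 passed over all genes by edgeR, and 18 were lower adjusted over the list alone. Mgp, a matrix protein gene, had 238 ± 28.5 CPM in controls and 69.7 ± 53.5 CPM in mutants (log2 fold change -1.77, SE 0.47, adjusted p 0.0820). The collagen genes Col3a1 and Col1a2 were at -1.55 and -1.48. The camera adjusted p was 6.15e-11, and adjusted p = 0.533 with an estimated correlation. The list mean was -2.43, -0.41 and -2.11 log2 units from control in mutant libraries 1, 2 and 3, and the median -2.42 without mutant library 2. Of 28 extracellular matrix genes Ncan, a proteoglycan gene of brain tissue, rose by 1.42 and Postn fell, and 11 passed adjusted over the list alone, 1 higher and 10 lower. The median was -1.01 (camera adjusted p 9.03e-07; adjusted p = 0.533 with an estimated correlation), and -1.61 without mutant library 2, with means of -1.45, -0.25 and -1.12 in mutant libraries 1, 2 and 3.

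Vessel markers were lower in mutant libraries 1 and 3. Of 22 endothelial genes Kdr, a receptor for vascular endothelial growth factor, fell by 1.54 (edgeR adjusted p 0.0418), and 3 passed adjusted over the list alone, with a median of -0.72 and Tek at -0.93. Camera gave an adjusted p of 6.94e-06, and adjusted p = 0.571 with an estimated correlation. Of 16 pericyte and smooth muscle genes 0 passed, or 2 adjusted over the list alone, with a median of -1.21, Acta2 at -1.70 and Myl9 at -1.37 (camera adjusted p 4.18e-06; adjusted p = 0.533 with an estimated correlation). The endothelial mean was -1.22, -0.15 and -1.19 and the pericyte mean -1.47, -0.45 and -1.74 log2 units in mutant libraries 1, 2 and 3. Of 25 gap and tight junction genes 0 passed, or 1 adjusted over the list alone, with a median of -0.69 (camera adjusted p 0.000503; adjusted p = 0.533 with an estimated correlation). Their mean was -0.95, -0.36 and -1.05 in the same order. Without mutant library 2 the pericyte median was -1.87 and the junction median -1.15.

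**Figure D2:**
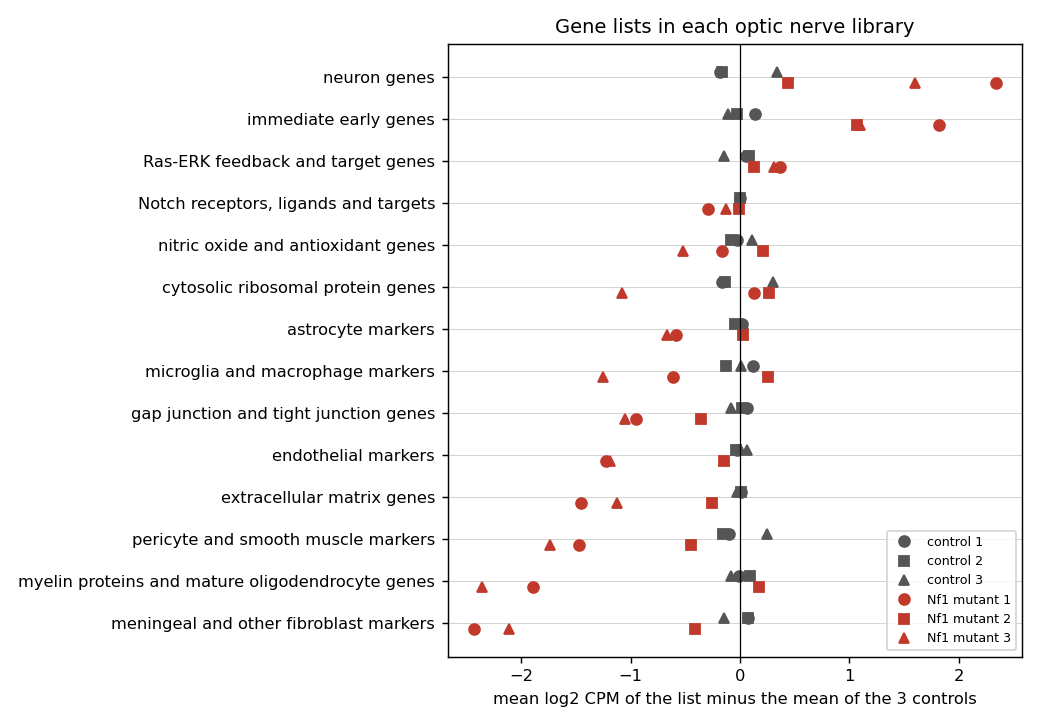
Mean log2 CPM of 14 gene lists in each library minus the mean of the 3 controls (grey, control libraries; red, Nf1 mutant libraries). Neuron genes stood at 2.34, 0.44 and 1.60 and fibroblast markers at -2.43, -0.41 and -2.11 in mutant libraries 1, 2 and 3, and myelin genes were at 0.17 in mutant library 2.

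Ras pathway genes, which neurofibromin acts on, were not called as a list. Of 29 feedback and target genes of Ras and ERK, Spry3, an inhibitor of receptor tyrosine kinase signalling, rose by 1.33 (SE 0.27, edgeR adjusted p 0.0374), and 3 were higher adjusted over the list alone. Egr1 was at 2.42 and Etv5 at 0.84, and the list median was 0.37 (camera adjusted p 0.124). Of 26 neurofibromin partners and Ras genes 2 rose, or 6 adjusted over the list alone, and the median was 0.20 (camera adjusted p 0.116). The Ras and ERK target median ranged from 0.22 without mutant library 3 to 0.53 without mutant library 2. The partner median ranged from 0.12 without mutant library 1 to 0.28 without mutant library 2. Of 29 Notch genes 0 passed in both families, with Hes5 at 1.30, Nrarp at 1.17, Jag1 at -0.77 and Notch1 at -0.69 (camera adjusted p 0.374).

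Nitric oxide genes split in direction. Of 27 nitric oxide and antioxidant genes the guanylate cyclase subunit genes Gucy1a3 and Gucy1b3 rose, by 2.53 (SE 0.30) and 2.08 (SE 0.36), with edgeR adjusted p 0.00451 and 0.0211. Adjusted over the list alone 4 were higher and 2 lower. Nos1, the neuronal nitric oxide synthase gene, was at 1.95, Ddah1 at 1.07 and the cystine transporter gene Slc7a11 at -1.08. The list median was -0.33 and its mean -0.05 (camera adjusted p 0.718).

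Markers of neighbouring tissues were not called by camera. Of 13 skeletal muscle genes Ryr1, a calcium release channel gene, rose by 2.94, and 2 passed adjusted over the list alone (median 0.13, camera adjusted p 0.751). Of 15 retina, pigment epithelium and melanocyte genes Rcvrn, the recoverin gene, rose from 0.0745 ± 0.0297 to 1.47 ± 0.340 CPM, and 1 passed adjusted over the list alone, with Rlbp1 at 0.98 (median 0.40, camera adjusted p 0.169). By fry, these 2 lists passed for change in either direction, with adjusted p 0.0436 for muscle and 0.00073 for retina. The retina median ranged from -0.15 without mutant library 3 to 0.64 without mutant library 2. Of 3 lens crystallin genes 0 passed in both families (median -0.50, camera adjusted p 0.479). Of 15 Schwann cell genes 0 passed, or 3 adjusted over the list alone, with Drp2 at 0.98 and Mpzl2 at -1.96 (median -0.85, camera adjusted p 0.141). Of 5 red blood cell genes 0 passed, or 1 adjusted over the list alone (median -0.22, camera adjusted p 0.751). The share of counts was higher in mutants for skeletal muscle genes, at 0.00589% against 0.00319% in controls. It was lower for lens (0.000545% against 0.000685%) and Schwann cell genes (0.0508% against 0.0730%). Each had an exact permutation p of 0.1 (0.267 adjusted), as had fibroblast and pericyte markers. Retina genes had p 0.5, and red blood cell shares also overlapped.

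Stress, cell cycle and housekeeping lists were also not called by camera with all 6 libraries at the preset correlation. Of 23 genes of the unfolded protein and amino acid response 0 passed in both families, with Asns at 1.51 (median -0.34, camera adjusted p 0.0668). Of 28 cell cycle genes 0 passed in both families, with Mki67 at 0.83 (median -0.01, camera adjusted p 0.604). Of 20 clock genes Npas2, a partner of Arntl, rose by 2.54 (edgeR adjusted p 0.00613) and was the 1 that passed adjusted over the list alone (median 0.14, camera adjusted p 0.610). Of 18 glucocorticoid-responsive genes 0 passed in both families, with Sult1a1 at -1.15. Their median was 0.13, while their mean was -0.07 and the camera direction was down (adjusted p 0.604). Of 38 nuclear genes of oxidative phosphorylation 0 passed in both families, with Ndufs3 at 0.43 (median 0.22, camera adjusted p 0.171). Of 46 ribosomal protein genes 0 passed in both families, with Rpl28 at -0.50 (median -0.13, camera adjusted p 0.124). On ranks camera called the unfolded protein (adjusted p 0.0140), oxidative phosphorylation (adjusted p 0.0122) and ribosomal protein lists (adjusted p 0.0456). Without mutant library 2 it called the unfolded protein (median -0.54, adjusted p 0.0486), glucocorticoid (-0.31, 0.0274) and ribosomal protein lists (-0.38, 0.0274), the last also without control library 2 (-0.18, 0.0400) or mutant library 1 (-0.28, 0.00583), and without mutant library 3 it called oxidative phosphorylation (0.43, 0.000268). In the other direction, the unfolded protein median was -0.14 without mutant library 3 and the oxidative phosphorylation median 0.05 without mutant library 1.

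Of the 31 lists tested, camera called 15 at the preset correlation, 2 higher and 13 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.533. By fry, 0 lists passed for change in 1 direction, with a lowest adjusted p of 0.143. Scaling to the myelin list moved the median of all genes by 1.78, and relative to that shift the skeletal muscle and glucocorticoid medians were -0.19 and -0.15. No other list median changed sign relative to all genes under RLE, upper quartile, total count or myelin scaling.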

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

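The results for mutant library 2 alone, for libraries with high Xist alone, with the neuron list mean as a covariate, without Rn45s, scaled to the myelin list and without X and Y genes were tests chosen after the results were seen. No paired analysis was possible because the labels give no shared replicate numbers. The planned share of counts without mitochondrially encoded genes gave no value, since none of those names was found. Adjustment for sex rests on control library 2, the 1 control with high Xist, and simulated 2-fold changes were recovered at 1.49%, so genes that did not pass are not shown to be unchanged.

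Against 537 genes changed, 482 higher and 55 lower, DESeq2 gave 1657, 1164 and 493, limma-voom with quality weights 4009, 1990 and 2019, no filter beyond 1 count 870, 745 and 125, and adjusted p under 0.10 1073, 868 and 205. With 1 surrogate variable the counts were 136, 131 and 5. The Xist covariate gave 0, 0 and 0, with 1304 genes at an unadjusted p under 0.05. Total counts gave 86 lower genes and limma-voom 88. Mutant library 2 against the 3 controls gave 222, 200 and 22, a group of 1 library that is assumed to vary like the controls, as for its lists below. Libraries with high Xist alone gave 0, 0 and 0 by edgeR, with 894 at an unadjusted p under 0.05. The neuron covariate gave 65, 61 and 4, and scaling to the myelin list 3183, 3179 and 4. Fewer residual degrees of freedom contribute to the lower counts with covariates or fewer libraries, and otherwise the cause was not tested. RLE, upper quartile scaling, robust dispersion, the CPM filter, and removal of tissue genes, Rn45s or X and Y genes gave 519 to 556 genes. The share of higher calls was 89.8%, against 70.2% with DESeq2, 49.6% with quality weights and 99.9% when scaled to the myelin list.

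Leaving out 1 library gave 51 to 4551 genes, 49 to 2226 higher and 1 to 2325 lower. All 6 libraries moved the count by over 1.5 times. Without control libraries 1, 2 and 3 it was 51, 81 and 112, and without mutant libraries 1, 2 and 3 it was 164, 4551 and 199. The 537 genes were all among the 4551. The Nf1 log2 fold change ranged from -0.51 to -0.03, and it was 1.75 when scaled to the myelin list (adjusted p 0.107), where the median of all genes was 1.78. The 12 genes named as higher passed in each leave-one-out fit. With the Xist covariate they did not, with adjusted p of 0.0926 to 0.114. With that covariate the median log2 fold change of the 482 genes was 2.55 against 2.44, and their median SE 0.68 against 0.41. The 482 were called from the same libraries, so the kept median is no test of sex.

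Under 1 surrogate variable the direction turned for Omg (0.56), Evi2a (0.46), Nrarp (-0.0078) and Mbp (0.55), none of which passed, and the cause was not tested. Omg ranged from -0.40 to 0.20 with 1 library left out. It was 0.01 without control library 2, 0.03 without mutant library 1 and 0.20 without mutant library 3. Of 1951 values of 103 named genes under the alternatives fixed beforehand, 1530 kept their direction and side of the threshold, 282 lost the call, 132 gained it and 7 turned direction.

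Camera called 15 lists, against 0 with an estimated correlation, 0 by directional fry, 2 by mixed fry, 19 on ranks, 16 with no filter beyond 1 count, 2 with the neuron covariate and 9 in mutant library 2 alone. It called 14 to 19 with 1 library left out. Skeletal muscle turned under the CPM filter (median -0.029) and without mutant library 2 (-0.25), ranging from -0.25 to 0.22. The camera direction of glucocorticoid-responsive genes turned up without control library 1 (median 0.27), mutant library 1 (0.15) or mutant library 3 (0.26), ranging from -0.31 to 0.27. That of nitric oxide genes turned without mutant library 3 (median -0.12), ranging from -0.83 to -0.12, and that of ribosomal protein genes without mutant library 3 (0.21), ranging from -0.38 to 0.21. The cause of these turns was not tested.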

Other observations

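The tests of the myelin and Trim patterns (that of dilution for the Trim genes was altered on the way, from Trim12a alone to 3 genes and then with a condition on well-counted members), and the results with the neuron covariate, were chosen after the results were seen, as were the genes and added lists named here. Qrfp, a neuropeptide gene among the 55 that fell, had 8.06 ± 4.84 CPM in controls and 0.791 ± 0.503 CPM in mutants (SD, n = 3 each; log2 fold change -3.34, SE 0.66, edgeR adjusted p 0.0322). Tshb, the thyrotropin beta subunit gene, had 6.36 ± 1.46 and 1.43 ± 0.266 CPM (log2 fold change -2.15, SE 0.42, adjusted p 0.0313). Hcrt, the orexin precursor gene, had 1.51 ± 0.964 and 0.0180 ± 0.0312 CPM (adjusted p 0.0307), and Nr5a1, a steroidogenic factor gene, had 1.24 ± 0.857 and 0.0180 ± 0.0312 CPM (adjusted p 0.0402). Of 23 tested genes in a list of hypothalamic and suprachiasmatic neurons 2 rose, Prok2 and Crh, and 1 fell, Hcrt, with a median of -0.60, and camera did not call the list (unadjusted p 0.123). Control nerves also held such transcripts, and 21 of the 23 had a control mean of at least 1 CPM. Avp had 309, 676 and 395 CPM in control libraries 1, 2 and 3, and 92.8, 624 and 30.2 CPM in mutant libraries 1, 2 and 3. Tissue from outside the nerve in the control libraries was not tested and stays open for these genes. Rnf135, on chromosome 11 at 80183872 to 80199753 beyond Nf1, fell by 1.72 (SE 0.37, adjusted p 0.0430). These 5 genes lost their calls without any 1 library other than mutant library 2, with adjusted p up to 0.216 for Rnf135, 0.179 for Qrfp, 0.168 for Tshb, 0.138 for Hcrt and 0.196 for Nr5a1.

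Genes of striatal projection neurons were higher in all 3 mutant libraries. In a list of 15 such genes made after their values were seen, all 15 rose, with means 4.41, 3.69 and 3.89 log2 units above control in mutant libraries 1, 2 and 3. In a second list of 25 genes, made without sight of their values, 10 rose, with a median log2 fold change of 1.68 (22 of 25 positive; camera unadjusted p 3e-15, and p = 0.00603 with an estimated correlation), and 22 of the 25 reached 1 CPM in control nerves. Gpr149 rose by 3.58 (SE 0.47), Ngef by 2.32 (SE 0.31) and Gpr6 by 4.48 (SE 0.67). Of the 3 other added neuron lists, the cortical and olfactory ones had medians as high and the hypothalamic one did not. Cortical neuron genes had a median of 1.71, with 14 of 16 positive and 2 that rose, Mef2c and Nrgn, and a mean of 2.96, 0.44 and 1.77 in mutant libraries 1, 2 and 3 (camera unadjusted p 1.07e-05, and p = 0.172 with an estimated correlation). Olfactory bulb and neuroblast genes had a median of 1.80, with 11 of 13 positive and 3 that rose, Dlx5, Sox11 and Meis2, which the first striatal list also holds, and a mean of 1.92, 0.23 and 1.97 (p 3.43e-05, and p = 0.128 with an estimated correlation). With the neuron list mean as a covariate the medians were -0.53 for the cortical and -0.06 for the olfactory list, and 3.62 and 0.90 for the first and second striatal lists, of which 15 of 15 and 0 of 25 passed. This does not set the lists apart by kind of neuron. The cortical and olfactory means were, like the covariate, highest in mutant libraries 1 and 3, so the covariate removes whatever marks those libraries. The 15 genes were listed after their values were seen.

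A candidate explanation of the striatal pattern is neural tissue from outside the nerve. Of the list made without sight of values, 40% rose, between the bounds set beforehand of 50% for such tissue and 10% against it, so this stays open. Simulated changes of 4-fold were recovered at 45.5% and of 2-fold at 1.49%, but the simulation made 33 calls against 537 in the data. Its cutoff on p was therefore stricter, and these rates may understate recovery in the data. How hard the bound of 50% was to reach with such tissue is thus not known. The share of 40% speaks neither for nor against it. Among abundant striatal transcripts Pde10a reached 577 CPM, Penk 265 CPM and Ppp1r1b 153 CPM in mutants. Sex of the animals is another candidate, and with Xist as a covariate the list median was 1.73 (median SE 0.63) against 1.68 (median SE 0.39), while all calls ended as the SE grew. That value met the bound set beforehand against sex, and control library 2, with high Xist, had means of -0.14 and -0.11 for the 2 lists against 3.69 to 4.41 and 1.25 to 1.89 in mutant libraries and 6.47 CPM of Drd1a against 73.3 to 143, but the bound was wrong for this design because these values rest on that 1 library, so sex also stays open. The Nf1 genotype was not tested separately and stays open as well. All mutants and no control carried the Cre, so Nf1 loss cannot be told apart from the Cre in any comparison here.

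Myelin genes were lower in mutant libraries 1 and 3, at -1.89 and -2.36 log2 units, and not in mutant library 2. Dilution of nerve RNA by neuron-rich RNA was tested with the neuron list mean as a covariate, where the median of the myelin list was 0.33 against -0.91. This decides nothing, since the neuron mean was highest in the 2 libraries that show the pattern, at 2.34 and 1.60 against 0.44 in mutant library 2, so the covariate removes whatever sets them apart. Lower values in mutant libraries 1 and 3 were not particular to myelin genes. Fibroblast markers were at -2.43 and -2.11 log2 units there, pericyte markers at -1.47 and -1.74 and endothelial markers at -1.22 and -1.19. Neuron and immediate early genes were higher there. Dilution and an effect of Nf1 loss both stay open.

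Within 3 Mb of chromosome 7, 4 genes fell, Trim6 (104218795 to 104235152; log2 fold change -3.41, SE 0.64), Trim12a, Trim12c (-1.44, SE 0.28) and Gm1966 (-2.31, SE 0.50). Against dilution, the mean of the 3 Trim genes minus that of the fibroblast list was -1.23, -2.71 and -0.69 log2 units in mutant libraries 1, 2 and 3 (mean -1.54 ± 1.05, SD, n = 3), but Trim6 and Trim12a had 0 to 6 counts in each of them. Trim12c, with 145 to 179, stood 0.49, -0.75 and 0.82 from the fibroblast list, so it was lower in mutant library 2 alone, and Trim12a, with 562 counts in controls and 7 in mutants, fell 54.1-fold (95% counting interval 26.1 to 135) where the fibroblast list fell at most 5.41-fold, which goes against dilution for that gene but rests on the gene of the group that fell most, so dilution stays open. A local genomic difference between the animals of the groups is a candidate, since 4 of the 55 fallen genes in 3 Mb was reached in 2.06% of 10000 random draws. That count rests on calls lost without 1 library (adjusted p up to 0.157 for Trim6, 0.0797 for Trim12a, 0.156 for Trim12c and 0.219 for Gm1966), and the draws ignore that related genes lie together and can share reads, which stays open, as does an effect of Nf1 loss.

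Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 537 genes and the highest other 0, and 1 split, the real one, gave as many. For lists the real split gave 15 and the highest other 20, and 4 of 10 gave as many. The splits are too few for a share under 0.05. The 2 splits with 20 lists put mutant libraries 1 and 3 with 1 control, against mutant library 2 with 2 controls, which points to a structure of the samples.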
